A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

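Cells of 4 Schizosaccharomyces pombe strains were fixed with paraformaldehyde, and sonicated chromatin was precipitated with an antibody to H3K9me3. Per the labels' protocols, precipitated DNA was labelled with Cy5 (red) and whole-cell extract DNA of the same cells with Cy3 (green) after random-primed amplification, and both were hybridised to an Agilent array of 60-base probes. The direction of every ratio is therefore immunoprecipitated over input. Per the file headers, all 4 arrays were on 1 slide and in 1 scan, so slide and scan do not differ between strains. The labels of IRD1 and IRD3 have the genotype and antibody values exchanged, so strains were taken from the titles.

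Per the file headers, spot intensity values were extracted with Agilent Feature Extraction 12.0.3.1, whose processed signals are background-subtracted and dye-normalized with linear dye factors. The deposited files also give the median intensity of each spot and of its local background, and a log10 ratio of red over green processed signal, which was not used for results. In the IRD1 and IRD3 files as deposited, processed signals are rounded to 3 significant digits. The deposited value table of the series holds a linear ratio of red over green that is not centred, with column medians of 1.11 in WT, 1.04 in IRD1, 1.11 in IRD2 and 1.06 in IRD3. Set against the arrays' own processed signals by feature number, its values differed by at most 0.01 on the log2 scale, so its scale, direction and lack of centring are known. All of its columns belong to the 4 samples.

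The main value was log2 of red over green processed signal, centred on the median of each array's genomic probes, with no loess, since many probes of a ChIP array can truly shift one way. The 1417 control spots per array were left out, as were spots marked as outliers by Feature Extraction, which were 1.13% of probes in WT, 7.33% in IRD1, 0.54% in IRD2 and 4.28% in IRD3. Probes whose input was not well above background had no ratio, and these were 7 in WT, 6 in IRD1, 7 in IRD2 and 6 in IRD3. Between 46 and 68 probes per array were not well above background in the immunoprecipitated channel and were kept. The noise between neighbouring probes outside the domains had an SD of 0.27 in WT, 0.31 in IRD1, 0.26 in IRD2 and 0.26 in IRD3. The number of arrays, 1 per strain, limits the precision of every comparison.

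The files name no genes, give no probe sequences and name no genome build. To learn whether the reference assembly (ASM294v3) could supply genes, input signal was set against the GC content of the reference in segments of 250 kb at shifts of up to 10 kb. The best shift ranged from -950 to 4400 bp on chromosome 1, from -1800 to -850 bp on chromosome 2 and from -1000 to 50 bp on chromosome 3, so the builds differ. No coordinates were converted. The planned counts of genes, gene lists and named genes were therefore not made, and non-overlapping windows of 1.5 kb with at least 3 probes took their place under the same rule. A window was counted when its median was at least 1 in one array and under 1 in the other and the difference was at least 1. Named windows are the 10 largest increases and decreases per comparison outside the mating-type domain, and those largest in all 3 comparisons, as fixed beforehand for genes. The text gives those that matter, and the counts of all.

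Domains were set from the WT array because no annotation could be used. A 5-probe running median of at least 3 marked heterochromatin, and runs up to 3 kb apart were joined. The mating-type domain was the run from 2131200 to 2138400 on chromosome 2 with that from 19800 to 39300 on the array's separate mating-type contig. Centromeres were the runs of the largest internal cluster of each chromosome, with gaps up to 20 kb allowed in a cluster. Flanks were 20 kb outward of the domain on chromosome 2, subtelomeres the outer 40 kb of chromosomes 1 and 2, and chromosome 3 ends the outer 20 kb. A difference from WT is the median over probes measured on both arrays. It was ranked among 10000 random runs of consecutive probes outside the domains with as many probes, up to 200, matched within 0.25 on the level of both arrays where at least 100 such runs existed. The first 5 probes outward of each edge were chosen as a region after the data were seen.

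The window rule was tested on simulated data made from the WT array with the noise of each comparison. Windows raised by 3 on the log2 scale were called in 100% of cases in all 3 simulated comparisons. Windows raised by 1.5 that could pass the threshold were called in 94.7% of cases for IRD1, 86.2% for IRD2 and 94.7% for IRD3, and 0 unchanged windows were called. This noise was drawn separately for each probe, so neighbouring probes never deviated together. The absence of false calls in the simulation therefore does not measure false calls on the real arrays. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, the authors' value table, loess within arrays, centring on euchromatic probes, scaling to equal centromeres, a filter on dim probes, probes without the suffixes f and m, means, narrower flanks and subtelomeres, a 3-fold threshold and a minimum of 5 probes per window. The files lack a mean signal, so normexp used the median signals. Without probe sequences, probes matching once were taken to be those without the suffixes f and m, whose meaning the files do not state. Keeping outlier spots, dropping probes with weak input, counting windows without a minimum difference and the thresholds of 2 and 3 for the extent were added after the data were seen. The analysis used R 4.3.3 with limma 3.58.1 for normexp and loess, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 for the rest.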

Results

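Histone H3 trimethylated at lysine 9 (H3K9me3), the mark of constitutive heterochromatin in fission yeast, was mapped by chromatin immunoprecipitation on tiling microarrays in Schizosaccharomyces pombe cells in exponential growth. There were 4 strains, called WT, IRD1, IRD2 and IRD3 in the labels, and each was measured on 1 array, so no difference below has a replicate check or a p-value. All 4 titles carry the same further tag, REIID, which the labels do not spell out. Each array held 41551 genomic probes at steps of 300 bp, and between 38502 (IRD1) and 41320 (IRD2) of them gave a usable ratio. Values are log2 ratios of immunoprecipitated over whole-cell extract (input) DNA, with the median probe of each array at 0. Ranges in parentheses are quartiles over probes, which describe the spread along a domain and not the error between cultures. Probe positions are those in the probe names, whose genome build the files do not give, so regions are named by position and not by gene.

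Every strain carried high H3K9me3 at the mating-type domain, the silent region of chromosome 2 that stores the unexpressed mating-type cassettes, and at the 3 centromeres. In WT the mating-type domain had a median of 5.88 (5.49 to 6.16) over 70 probes, which is 58.8 times the array median, and the centromeric repeats had 6.39 (5.83 to 6.71) over 198 probes. The corresponding medians were 5.91 and 6.27 in IRD1, 5.06 and 5.90 in IRD2, and 5.70 and 6.34 in IRD3. Subtelomeres, the outer 40 kb of chromosomes 1 and 2, had a median of 3.76 (0.08 to 4.48) in WT. It was 4.37 (0.87 to 5.02) in IRD1, 4.37 (0.985 to 4.96) in IRD2 and 4.29 (1.10 to 4.98) in IRD3. The ends were unlike in level, so a pooled median does not describe an even enrichment. In WT the left and right ends had medians of 5.15 and 4.29 on chromosome 1, and 0.155 and -0.007 on chromosome 2. The pooled levels rest on probes with the suffix f or m in their names, whose meaning the files do not state. Without them the subtelomeres had 0.49 in WT, 3.42 in IRD1, 0.93 in IRD2 and 1.73 in IRD3. Probes outside these domains had a median of -0.02 on each of the 4 arrays. Mitochondrial probes, which carry no histones, gave the background of the immunoprecipitation, at -1.66 in WT, -1.74 in IRD1, -1.98 in IRD2 and -2.20 in IRD3. Across all probes, pairs of arrays correlated with Pearson's r of 0.945 to 0.971, where probes are not independent replicates.

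The input channel reads the DNA present, with or without the mark, and showed several probes with almost no signal. On chromosome 2 of all 4 arrays, the 4 probes from 2133000 to 2133900, inside the mating-type domain, had input signals between -10.59 and -6.29 relative to the array median on the log2 scale. The probe at 2117100 was also without input on all 4 arrays. Probes at the 2 edges of the domain then set the strains apart. IRD2 had lost the input at 2131200, the outermost probe of the left edge in WT (-8.16, against -0.33 in WT), and at 2138400, the outermost probe of the right edge (-7.95 against -0.33). It also lacked input at 39300 on the array's separate mating-type contig (-7.89 against -0.16). Without probe sequences, it was not tested whether this contig covers the same DNA as the domain on chromosome 2. IRD1 had lost the input of the next probe outward on the right, 2138700 (-7.21 against -1.11 in WT). IRD3 kept the input of all these probes and lost it at 19800 (-6.36 against -0.46) and 39000 (-5.80 against 0.38) on the mating-type contig. WT kept the input at all 6 of these positions. The probes that IRD1 and IRD2 had lost gave no ratio there and were not compared. The 2 weak probes of IRD3 still counted as above background and kept ratios of 3.79 at 19800 and 4.03 at 39000, which rest on little input. Leaving out probes with weak input, an alternative added after the data were seen, moved 0 of 61 values beyond the limits set for the alternatives.

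The first comparison asked whether H3K9me3 inside the mating-type domain differed between each IRD strain and WT. IRD2 was lower, with a median difference of -0.68 (-0.93 to -0.52) over 67 probes, and 1 of the 67 probes was higher than in WT. IRD1 differed by -0.02 (-0.12 to 0.10) over 70 probes and IRD3 by -0.13 (-0.28 to 0.00) over 70 probes. The lower level of IRD2 held on the chromosome 2 part of the domain (-0.70, 19 probes) and on the mating-type contig (-0.64, 48 probes). IRD2 lost input at the right edge of both parts, at 2138400 (-7.95) and at 39300 (-7.89). The 2 parts may therefore read the same DNA, which could not be tested without probe sequences, so they are not separate checks. Among 10000 random runs of as many consecutive probes outside the domains, 95% of the IRD2 differences lay between -0.25 and 0.17. No such runs with an equally high H3K9me3 level exist, so those runs describe low-level chromatin. Centromeres were also lower in IRD2, by -0.45 (-0.56 to -0.29) over 197 probes, against -0.10 in IRD1 and -0.05 in IRD3. With each array scaled to equal centromere levels, the difference of IRD2 inside the mating-type domain was -0.25, and with loess within each array it was -1.91. The centromere difference of IRD2 was -2.62 with loess and -0.20 over probes without the suffixes f and m in their names. The corresponding values were -0.46 and -0.26 in IRD3, and -0.06 and 0.05 in IRD1. Over probes without those suffixes the centromeres were thus lower in IRD3 than in IRD2.

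**Figure D1:**
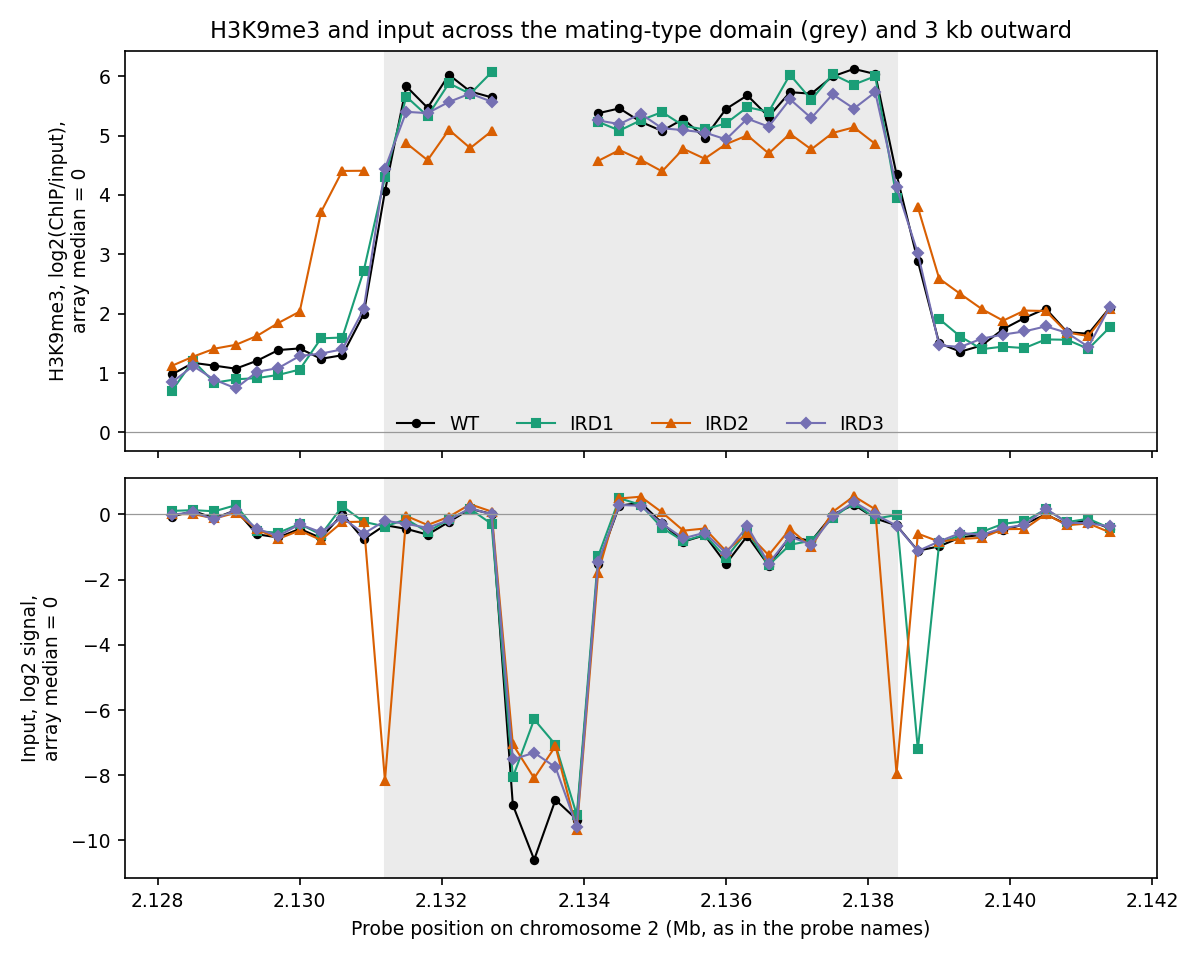
The upper panel plots the log2 ratio of immunoprecipitated over input DNA and the lower panel the log2 input signal, both centred on the array median, against probe position on chromosome 2, with 1 line per array and the mating-type domain in grey. Ratios of probes with input 3 or more below the median are not drawn. IRD2 lies below WT inside the domain. It lies above WT on every probe drawn to the left and up to 2140200 on the right. The input of IRD2 falls to -8.16 and -7.95 at the 2 edge probes.

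Immediately outside the domain the direction turned in IRD2. The edges were drawn where the WT running median fell below 3, and the same WT array was then subtracted. This choice can by itself favour lower values inside and higher values just outside in any strain. The first 5 probes left of the domain were higher in IRD2 by a median of 2.42 (0.62 to 2.47), and all 5 were higher than in WT. At 2130600, the ratio was 4.41 in IRD2, 1.30 in WT, 1.60 in IRD1 and 1.399 in IRD3. At 2130900, it was 4.41 in IRD2, 1.99 in WT, 2.72 in IRD1 and 2.07 in IRD3. The first 5 probes on the right were higher in IRD2 by 0.91 (0.61 to 0.97), again on all 5 probes. Of random runs of 5 probes outside the domains, 95% of the IRD2 differences lay between -0.56 and 0.41 for the left side. Only 12 runs there matched on level, under the minimum of 100, and 3 of them differed by 1 or more, all in windows gained in all 3 IRD strains, so these runs were not matched. Runs matched on level could not judge the right side: 15 of the 376 runs differed by 1 or more, and all 15 lay in windows gained in all 3 IRD strains. With loess within each array the rise was 0.82 on the left and 0.48 on the right. Over the same probes the median difference was 0.30 on the left and 0.09 on the right in IRD1, and 0.08 on both sides in IRD3. The right value of IRD1 rests on 4 probes, since 2138700 had lost its input. Going outward, the IRD1 differences ran from 0.41 at 2139000 to -0.29 at 2139900 on the right. On the left they ran from 0.73 at 2130900 to -0.42 at 2129700. The IRD1 value on the left lay above its range of matched runs (-0.66 to 0.17), and was 0.11 with normexp and 0.12 with means. The other 3 lay within their ranges. The probe at 19200 on the mating-type contig showed the same order, with 4.32 in IRD2, 2.63 in IRD1, 1.90 in IRD3 and 1.68 in WT. That probe may read the same DNA as the probes left of the domain, so it is not a separate check. From 1.5 to 3 kb outward the IRD2 difference was 0.29 on the left and -0.02 on the right.

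Over 20 kb, the quartiles of the difference from WT lay on either side of 0 for both flanks in every IRD strain. The median of the left flank differed by -0.13 in IRD1, -0.11 in IRD2 and 0.02 in IRD3, and the right flank by -0.17, -0.09 and -0.04. Within 10 kb the left flank differed by -0.07, 0.12 and 0.03, and the right flank by -0.36, -0.31 and -0.12. The values over 20 kb fell between the 31.7 and 82.3 percentiles of random runs matched on H3K9me3 level. At a 2-fold threshold (1 on the log2 scale) the unbroken run of enriched 5-probe medians reached 2.7 kb beyond the left edge in WT, 1.2 kb in IRD1, 3 kb in IRD2 and 2.1 kb in IRD3. On the right it reached 5.1 kb in WT, IRD2 and IRD3 and 4.8 kb in IRD1. At a threshold of 2, chosen after the data were seen because WT itself stays near 1.5 outside the right edge, the run reached 1.2 kb on the left in IRD2 against 0 kb in WT and 0.3 kb in IRD1 and IRD3. On the right it reached 1.8 kb in IRD2, 0.3 kb in WT and IRD3 and 0 kb in IRD1.

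**Figure D2:**
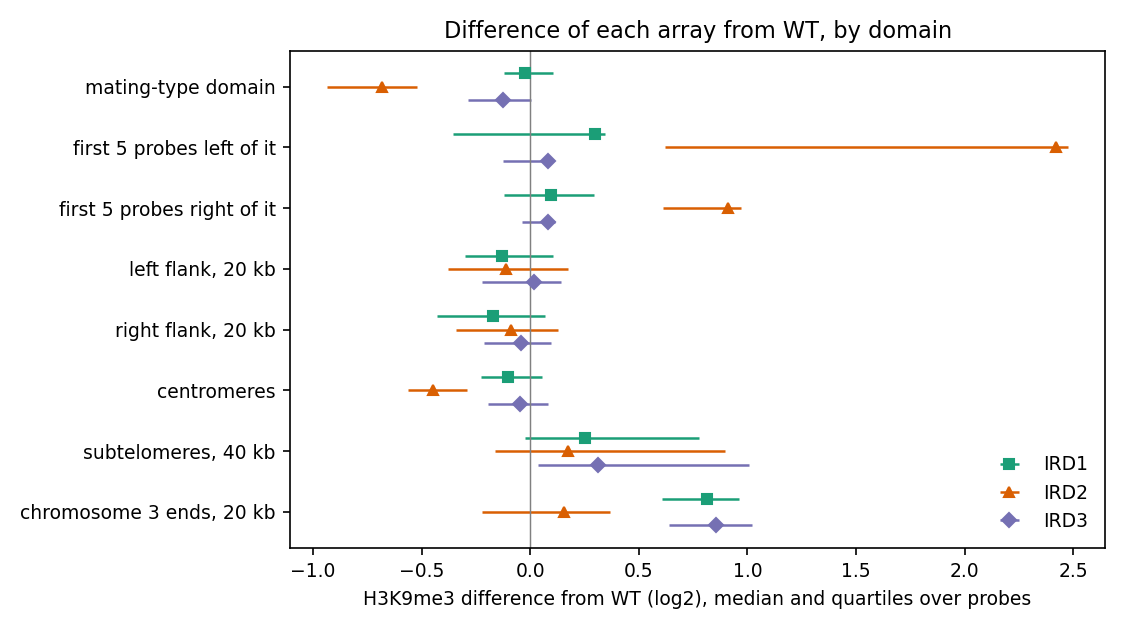
Each point is the median over probes of the log2 ratio in one IRD array minus that in WT, and bars span the quartiles over probes. IRD2 has the lowest mating-type domain (-0.68) and the highest first probes on its left (2.42) and right (0.91). The same signs appear at smaller size in IRD1 (-0.025, 0.30 and 0.09) and IRD3 (-0.13, 0.08 and 0.08). Behind each symbol stands 1 array.

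At the subtelomeres the median difference from WT was 0.25 (-0.02 to 0.78) in IRD1, 0.17 (-0.16 to 0.90) in IRD2 and 0.31 (0.04 to 1.005) in IRD3, so the quartiles of IRD1 and IRD2 span 0. The size depended on the processing: the outer 20 kb gave 0.14, 0.04 and 0.105, means over probes gave 0.54, 0.44 and 0.605, and loess within each array gave -0.21 in IRD2 and 0.16 in IRD3. By chromosome end, in the order chromosome 1 left and right and chromosome 2 left and right, the median differences were 0.04, 0.30, 0.16 and 0.43 in IRD1, -0.02, 0.18, 0.14 and 0.26 in IRD2, and 0.14, 0.37, 0.15 and 0.61 in IRD3. The pooled differences lay above at least 99.59% of random runs of 200 probes outside the domains, which do not match the subtelomeres on level. In each comparison the window with the largest rise lay near the inner border of the right end of chromosome 1. For IRD1 it was 5535000 to 5536500, inside the outer 40 kb, and for IRD2 5532000 to 5533500, inward of it. For IRD3 it was 5533500 to 5535000, across that border. The interval from 5526000 to 5536500 was set by windows counted as gained in all 3 IRD strains. A WT window median under 1 and a rise of at least 1 there therefore follow from the choice. From 5526000 to 5536500, 35 probes had a median of 0.24 (-0.02 to 0.59) in WT, 2.81 (2.33 to 3.41) in IRD1, 3.52 (3.00 to 4.07) in IRD2 and 3.92 (3.505 to 4.57) in IRD3. The median of the differences per probe was 2.72 in IRD1, 3.38 in IRD2 and 3.79 in IRD3, which is 6.56, 10.4 and 13.8 times WT. Running medians at or above 2 reached 34.2 kb inward from the last probe in WT, 46.2 kb in IRD1, 48.9 kb in IRD2 and 49.2 kb in IRD3. At the left end of chromosome 1 the run at that threshold reached 36.3 kb in WT, IRD1 and IRD3 and 36.6 kb in IRD2. At a threshold of 1 it reached 36.3 kb in WT and 41.4 kb in each IRD strain, and at a threshold of 3 it reached 25.2 kb and 36.3 kb. Nearer the end, at 3000 to 4500 on chromosome 2, the window median was 2.73 in WT, 5.13 in IRD1, 4.83 in IRD2 and 4.496 in IRD3. The enriched ends of chromosome 2 reached equally far inward in WT, IRD1 and IRD3 at a threshold of 2, at 15.6 kb on the left and 11.7 kb on the right, and 15.9 kb and 12 kb in IRD2. At a threshold of 1 the right end reached 11.7 kb in WT, 17.1 kb in IRD1 and IRD2 and 24.3 kb in IRD3, and the left end 15.6 kb in WT, 16.5 kb in IRD1, 18.6 kb in IRD2 and 15.9 kb in IRD3. The ends of chromosome 3, the outer 20 kb, were higher by 0.81 in IRD1 and 0.86 in IRD3, and by 0.15 in IRD2.

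**Figure D3:**
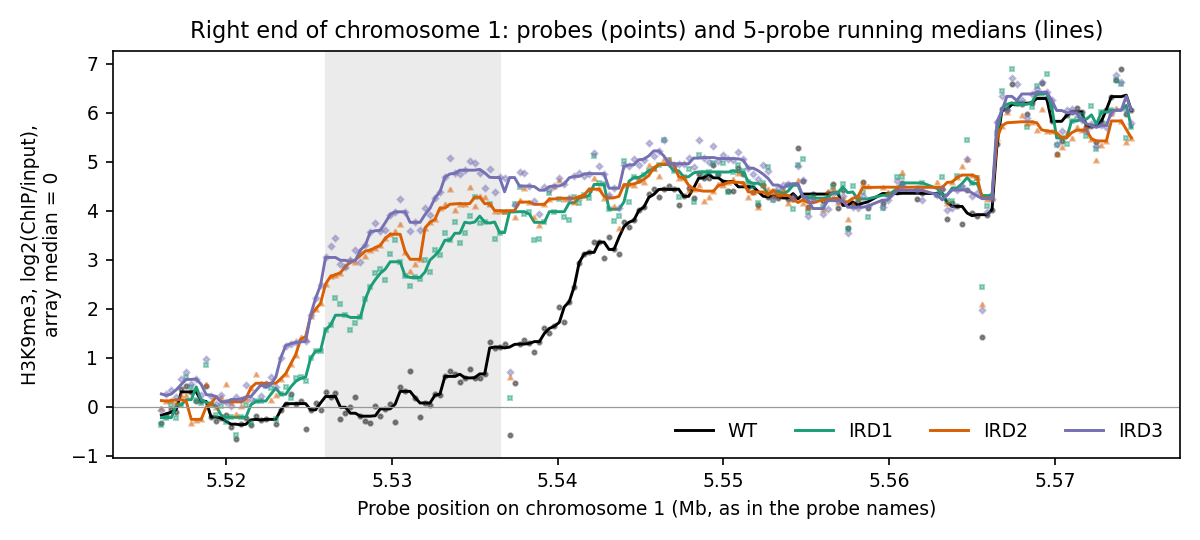
Points are probes and lines 5-probe running medians of the log2 ratio of immunoprecipitated over input DNA along the right end of chromosome 1, 1 colour per array. In the grey interval, 5526000 to 5536500, WT has a median of 0.24 while IRD1, IRD2 and IRD3 have 2.81, 3.52 and 3.92. The 4 lines meet nearer the chromosome end, and from 5568600 outward IRD2 lies lowest at most but not all probes.

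Genome-wide, 8173 windows of 1.5 kb held at least 3 probes, and 972 of them had a median of at least 1 in WT, 552 in IRD1, 916 in IRD2 and 758 in IRD3. The upper quartile of probes outside the domains followed the same order, at 0.63, 0.50, 0.61 and 0.56. Counts at this threshold alone therefore cannot separate a change of the mark from a wider spread of ratios on an array. A window was counted as gained or lost when it was at least 1 in one array, under 1 in the other and different by at least 1. By this rule 13 windows were gained against WT in IRD1, 14 in IRD2 and 21 in IRD3, and 3, 5 and 1 were lost. These counts depended on the processing, as given below. With loess within each array more windows were lost in IRD2, and without suffix f or m fewer were gained in IRD1 and IRD2. Without the minimum difference, chosen after the data were seen, 54, 208 and 83 windows were at least 1 in the IRD strain alone, and 474, 264 and 297 in WT alone. Of the windows gained in any of the strains, 9 were gained in all 3, and 7 of these lay in the interval at the right end of chromosome 1. The others were 36000 to 37500 on chromosome 1 and 76500 to 78000 on chromosome 2. In the latter, the window median was 0.00 in WT, 2.27 in IRD1, 2.97 in IRD2 and 3.49 in IRD3. Its lower quartile was -0.17 in IRD1, -0.65 in IRD2 and -0.53 in IRD3, so part of its probes stayed below 0. All 5 probes of the former and 3 of the 5 of the latter carry the suffix f or m in their names, which was frequent among enriched probes. Median input was 0.43 for suffix f, 1.7 for m and -0.02 for other probes. Whether either window reads sequence shared with the interval on chromosome 1 was not tested. IRD1 and IRD2 shared 11 gained windows, IRD1 and IRD3 shared 10, and IRD2 and IRD3 shared 10. Independent lists would share 0.02 to 0.04 windows, and simulated unchanged arrays set against 1 common WT array shared 0. Both figures take no account of neighbouring windows rising together, and 7 of the 9 windows gained in all 3 lay in the same interval. They therefore cannot judge the overlap. The simulation held probe noise alone and gained on average 0 to 0.14 windows over 100 draws, so it does not cover a deviation of the WT culture, from which part of the overlap can come, since all 3 comparisons rest on the same WT array.

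Without the minimum difference, 163 windows were at least 1 in WT and under 1 in all 3 IRD strains, and 22 the other way round. The wider spread of ratios outside the domains in WT cannot be told apart from a loss of the mark here. With the minimum difference, 1 window was lost in all 3. It lay within centromere 3, from 1095000 to 1096500, between the repeat blocks of the centromere, and had a window median of 1.49 in WT, -0.84 in IRD1, -0.79 in IRD2 and -0.55 in IRD3. All 5 of its probes carry such a suffix, and their input was higher than in WT by 0.43 in IRD1, 0.42 in IRD2 and 0.45 in IRD3. Outside the mating-type domain the largest fall in IRD2 was at 274500 to 276000 on chromosome 3, from 3.20 in WT to 0.75. This window holds the border of an isolated enriched run from 275400 to 276900, which itself had medians of 5.98 in WT and 5.28 in IRD2. In IRD1 and IRD3 the largest fall was the centromere 3 window, by -2.33 and -2.04.

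The IRD strains were not replicates of one another and were compared as 3 genotypes. Inside the mating-type domain, IRD1 exceeded IRD2 by 0.74 (0.48 to 0.96) and IRD2 lay below IRD3 by -0.56 (-0.73 to -0.44), while IRD1 and IRD3 differed by 0.13 (-0.03 to 0.30). The first 5 probes left of the domain gave -1.69 for IRD1 minus IRD2, 2.34 for IRD2 minus IRD3 and 0.20 for IRD1 minus IRD3. At the subtelomeres the 3 pairwise medians were between -0.12 and 0.09. At the right end of chromosome 1 the rise over WT was smallest in IRD1 (2.72), intermediate in IRD2 (3.38) and largest in IRD3 (3.79).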

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

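The tests of input DNA and of strain background in this part were chosen after the results were seen, while leaving out probes with the suffixes f and m was fixed beforehand as an alternative. The array also carries probes for separate clones named pNSU, which the comparisons of domains did not use, and some of these had higher H3K9me3 in the IRD arrays than in WT. The pNSU32 clone, with 3 probes, was higher by 1.59 in IRD1, 1.04 in IRD2 and 1.53 in IRD3, from a WT median of 3.34. The pNSU77 clone, with 23 probes, had median differences from WT of 1.01 in IRD3, 0.70 in IRD1 and -0.21 in IRD2. Its median level was 2.34 in WT and 3.58 in IRD2, so the level and the differences per probe disagree in direction for IRD2.

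The right end of chromosome 1 was also higher in all 3 IRD arrays. Less input DNA in the IRD strains would raise the ratio there, but the largest fall of the median input over the region was -0.18, far short of the smallest rise in the ratio, 2.72. Over the 31 probes with no suffix f or m the smallest median rise was 2.78, but the files do not state what the suffixes mean, so sequence shared with other places was not tested. A difference in strain background between WT and the IRD strains may underlie the pattern and cannot be told apart from an effect of the IRD genotypes: 4 probes, on the clones pNSU21 and pNSU65, had input 3 or more below the median in WT alone, which shows that WT differs from the other strains in some of this sequence but not that this sets H3K9me3 on chromosome 1. An effect of the genotypes themselves stays open, with 1 WT array as the only control.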

How the results depend on the processing

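No paired analysis was possible because each strain has 1 array and no result comes from a test, and leaving out a replicate was not possible for the same reason. All arrays hold the same probes, so comparing by probe name moved nothing. A value was taken to have moved when it changed by more than 1 SD over the probes of its domain, by more than 1.5 kb for an extent, or by more than 1.5 times for a count. Of 634 values recomputed, 579 stayed within these limits, 55 moved and 0 turned a difference larger than its SD. The authors' value table, the filter on dim probes, keeping outlier spots and dropping weak input each left all 61 of their values within the limits. The authors' value table holds nearly the same ratios as the main analysis, so its values could hardly move. An SD over probes is a spread along a domain and not an error between cultures. Of 276 differences, 18 changed sign, each smaller than its SD in the main analysis. Of these, 2 ended beyond it: IRD1 at the isolated chromosome 3 run, with -0.15 by normexp and -0.18 by loess. The rise of IRD2 left of the mating-type domain ranged from 0.82 to 2.78 over the settings, its fall inside from -1.91 to -0.25, and the rise at the right end of chromosome 1 was at least 2.07 in each strain and setting. The interval at that right end was chosen for its rise in these data, so part of its size follows from the choice. The extents at the 2-fold threshold stayed within the limit in every setting that recomputed them. Loess within arrays, which by construction draws high ratios of bright spots toward 0, moved most. With it the mating-type levels were 4.05 in WT, 3.91 in IRD1, 2.13 in IRD2 and 3.66 in IRD3, the centromere levels 3.91, 3.79, 1.37 and 3.40, and the subtelomere level of IRD2 1.19. Differences from WT with loess were -1.91 for the IRD2 mating-type domain, -2.62 and -0.46 for the centromeres of IRD2 and IRD3, and 0.82 and 0.48 for the first probes left and right of the domain in IRD2. Windows enriched in WT only numbered 24 against IRD2 and 0 against IRD3 with loess. Scaling to equal centromeres gave -0.25 for the IRD2 mating-type domain. With probes lacking the suffixes f and m, centromere levels were 5.13 in WT, 5.04 in IRD1, 4.71 in IRD2 and 4.64 in IRD3, their differences from WT -0.20 in IRD2 and -0.26 in IRD3, and subtelomere levels 0.49 in WT, 3.42 in IRD1, 0.93 in IRD2 and 1.73 in IRD3. The same probes gave 8 windows gained in IRD1 and 7 in IRD2, and 1 and 0 lost in IRD2 and IRD3, with fewer windows to test. Flanks of 10 kb gave a right flank of 1.501 in WT, differences there of -0.36, -0.31 and -0.12 in IRD1, IRD2 and IRD3, and a left flank difference of 0.12 in IRD2. Normexp gave -0.034 for the first probes on the right in IRD3 and 0 windows lost in IRD3. Centring on euchromatic probes gave 5 windows lost in IRD1 and 2 in IRD3, and means gave 3 lost in IRD2. The 3-fold threshold gave 0, 1 and 0 windows lost in IRD1, IRD2 and IRD3 and 12 gained in IRD3. Without a minimum difference, chosen after the data were seen, 54, 208 and 83 windows were gained in IRD1, IRD2 and IRD3 and 474, 264 and 297 lost. A minimum of 5 probes gave 3 lost in IRD2 and 13 gained in IRD3. Where no construction is named above, the cause was not tested. Signal limited few probes, with at most 7 per array not well above background in the input.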

Other observations

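The tests of a smaller range of ratios, of input DNA and of a second copy in this part were chosen after the results were seen, while scaling to equal centromeres and loess were fixed beforehand as alternatives. Away from the domains and chromosome ends, 4 runs of probes reached a running median of 3 in at least 1 array. The run from 4907700 to 4908300 on chromosome 1 had medians of 5.91 in WT and 5.32 in IRD2, and all 3 of its probes carry the suffix f or m. The run from 275400 to 276900 on chromosome 3 had 5.98 in WT, and all 6 of its probes carry such a suffix. Among all probes, 27.6% of those with suffix f and 41.2% of those with suffix m had a mean ratio of at least 3, against 0.47% of the others. The run from 2340600 to 2341200 on chromosome 2, with no such probe, was 1.99 in WT, 3.51 in IRD1, 3.26 in IRD2 and 3.66 in IRD3.

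The lower level of IRD2 inside the mating-type domain and its higher level just outside were weighed against technical explanations. The drawing of the edges from the WT array, which can favour both, was not tested. A smaller range of ratios on the IRD2 array would lower every strongly marked domain, and after scaling to equal centromeres the difference inside was -0.25 with quartiles of -0.52 and -0.10 and an SD over probes of 0.31, so this cannot be told apart from a lower level in the domain. It predicts lower values outside too, where the first 5 probes on the left rose by 2.42, or 0.82 with loess. Less input DNA there is argued against by an input difference of -0.051 over those probes. IRD1, which lost a probe outside the right edge, rose there by a median of 0.09 over the 4 probes left, with 0.41 at the nearest. IRD3, with weak input at 2 mating-type probes, rose by 0.08 on both sides. The probes with lost or weak input in IRD1 and IRD3 are other probes than those lost in IRD2. In IRD2, 1 probe at each edge of the domain had lost its input. A hypothesis that was not tested and stays open is that sequence at these probes normally keeps the mark inside. One strain on 1 array cannot separate it from other differences of that strain.

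The fourth run, from 115500 to 116700 on chromosome 3, had medians of 5.73 in WT, 5.69 in IRD1, 4.34 in IRD2 and 5.70 in IRD3. Its median input was -0.40, -0.03, 0.06 and -0.60 in the same order. Input was higher than in WT in both IRD1 and IRD2, while the ratio of IRD1 differed from WT by 0.03. Whether the higher input contributes to the lower ratio of IRD2 was not tested. None of the 5 probes of the run carries the suffix f or m, whose meaning the files do not state, so repeated sequence was not tested. A candidate explanation is that its probes read a second copy of the sequence placed in the mating-type domain of all 4 strains. The difference of IRD2 from WT, -1.37, lay below all medians of 5 consecutive probes both in the mating-type domain (-1.13 to -0.42) and in the centromeres (-0.68 to -0.11), so such a copy cannot be told apart from a change at the run itself or in the number of its copies. On the left arm of chromosome 3 the probe positions matched the reference assembly ASM294v3 within 50 bp, which would place the run on ura4, a marker gene often used as a reporter, though without probe sequences this match rests on position alone.

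Probes beside that run also differed between strains. At 115200 the ratio was 2.58 in IRD1 and 1.83 in IRD2, against 0.48 in WT and 0.18 in IRD3. At 117000 it was 1.98 and 1.52, against 0.23 and -0.23, while the input there was -1.25 in IRD1 and -1.25 in IRD2, against -0.35 in WT and -0.48 in IRD3.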
